A study of Talinum fruticosum with 36 samples.

How the data were processed

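Leaf RNA was made into polyA-selected libraries and sequenced by the authors on an Illumina HiSeq 2000 with 12 libraries per lane, in single reads of 150 bp, per the labels. The lane of each library was not given. The authors called bases with CASAVA 1.8.2. Per the file headers, the authors mapped the reads in protein space with BLAT against a reduced set of Arabidopsis TAIR10 proteins and assigned each read to its best match. The deposited table of loci gives the raw read count of each library and Arabidopsis locus, and these counts are the values tested here. The deposited score of the same table is each count scaled by the authors to the library total (RPM) and rounded, and it equalled the rounded CPM in 100% of the cells, with a largest difference of 0. The log2 fold changes and q-values in the deposited table came from the authors' DESeq2, whose version was not given, and are used here only to count the loci that the authors' table lists at a q-value under 0.01. A second deposited table gives the authors' mean RPM per group for 39781 contigs of a de novo assembly, with the authors' log2 fold changes and q-values. Of these, 36298 had an Arabidopsis match, to 12276 loci. The tool that mapped reads to contigs was not stated. No reference genome was used. The 6 paired-end libraries, 1 per condition, were not analysed here.

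The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Loci were kept by filterByExpr, which left 14052 of 21869 (5103 had no count in any library), and TMM factors were used. The fit was robust, with 1 coefficient for each of the 10 groups, all 30 libraries and 20 residual degrees of freedom, and the biological coefficient of variation was 0.173. The test was made for 17 contrasts: each stage against day 0 and re-watering against day 12 at each time of day, midnight against midday within each stage, and the difference between the midnight and the midday response on days 9 and 12. Adjusted p is the Benjamini-Hochberg value within a contrast, tests are two-sided, and a locus was called at an adjusted p under 0.05. The contrasts between a pair of groups compare 3 libraries with 3, where an exact permutation test of a single locus could not pass the threshold. The p-values rest on the edgeR model across loci.

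The gene lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined. The lists were 23, with 436 Arabidopsis loci, of which 341 were in the table and 329 were tested (12 were left out by the filter on low counts). They were C4-acid and CAM carbon cycle, photosystems and light harvesting, Calvin-Benson cycle, photorespiration, starch degradation, starch synthesis, glycolysis, vacuolar proton pumps, abscisic acid synthesis and turnover, abscisic acid signalling, drought response markers, circadian clock, nitrogen assimilation, aquaporins, senescence and chlorophyll breakdown, expansins and cell cycle, heat shock and chaperones, antioxidant enzymes, wax and cuticle, and markers of guard cells, vasculature, epidermis and defence. Lists with at least 3 measured members, 21 in all, were tested against the other loci with camera of limma 3.58.1, with a preset correlation between genes of 0.01, on log2 CPM with a prior count of 2, and adjusted over the lists of a contrast. The same test with an estimated correlation, and fry, were run beside it. Of 126 list calls with the preset correlation, 0 held with an estimated one, at which limma gave 0 calls in all contrasts, while fry called 185.

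Genes were named by the following rule. For each contrast against day 0 or day 12 the 5 called loci with the largest increase and the 5 with the largest decrease were taken, 10 and 10 on day 9, if a group mean was at least 10 CPM and the 3 libraries of one group all lay above those of the other. For midnight against midday and the interactions it was 5 and 5. In addition, every called member of the CAM list on day 9 and, of each other list, the 4 called members with the smallest adjusted p in a contrast could be named. Members that were not called are given with values only. Not every locus that the rule takes is reported here.

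The alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma-trend on log2 CPM, no filter, a filter of 5 CPM in 3 libraries, an adjusted p under 0.01, a log2 change of at least 1, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Leaving out both libraries that correlated least with their groups was added after the data were seen. Overlaps were set beside the product of the list sizes over the number of loci tested and beside 20 draws of simulated unchanged groups that share the control libraries.

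The replicate numbers did not pair libraries. Of 135 pairs with the same number in different groups, 20 had a residual correlation above 0.1 (mean r = 0.002 across loci, compared with -0.001 for other pairs, range -0.41 to 0.378), and 7 of the 30 libraries correlated best with their own number. The tests were tested on simulated data with 200 changed loci of 14052. The edgeR test found 62% of the 2-fold and 92% of the 4-fold changes between a pair of groups, with 9 unchanged loci among 163 calls, and 29% and 78% in an interaction, with 3 among 110. In a contrast without change edgeR and limma-trend called 0 and DESeq2 called 1. Each list test found the 1 raised list (15 members, 1.5-fold) of 23 and called no other. The simulated loci were drawn independently of each other. The simulation therefore does not show how the list tests behave where genes vary together.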

Results

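Leaf transcripts of Talinum triangulare, a herb that can switch from ordinary daytime carbon fixation to crassulacean acid metabolism (CAM), were counted during drought and recovery. In CAM, stomata open at night, carbon dioxide is fixed by phosphoenolpyruvate carboxylase and stored as malate, and the malate is decarboxylated in the light. The plants were kept well watered for 28 days and then left without water. Mature leaves were taken on days 0, 4, 9 and 12 of drought and after 2 days of re-watering that followed 12 days of drought. Each stage was sampled at midday and at midnight, 6 h into the light and the dark phase. This gave 10 groups with 3 biological replicates each and 30 single-end libraries. No plants kept watered to the later days were among the libraries. In comparisons with day 0, drought, plant age and sampling day can therefore not be told apart. The labels assign the day 9 and day 12 plants to the CAM mode and the others to ordinary photosynthesis. A further 6 paired-end libraries, made for the assembly of the transcriptome, were not analysed here.

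The libraries held between 4266915 and 8756533 counts over Arabidopsis loci. Of 21869 loci in the table, 16766 had a count in at least 1 library and 14052 passed the filter on low counts. The lowest level that a library could exclude at a count of 0 (3 counts) lay between 0.343 and 0.703 CPM, for counting error only. Levels are given as normalised counts scaled to a common library size (CPM), mean ± SD over 3 libraries, and changes as log2 fold changes ± standard error with the Benjamini-Hochberg adjusted p of the edgeR quasi-likelihood test. The standard error was derived from that test, as the absolute log2 fold change over the square root of the F statistic. Members of a gene family may share reads, because reads of Talinum were assigned to their best Arabidopsis match. The values of PPC1 and PPC2, NADP-ME1 and NADP-ME4, DIC1 and DIC2, GPT1 and GPT2, the PFK loci, IPGAM1 and IPGAM2, the nitrate reductases, the inositol oxygenases and the germins are therefore uncertain as to the single locus.

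The first 2 principal components held 39.9% and 30.2% of the variance of the log2 values. Libraries of one group correlated with each other at r between 0.951 and 0.989 across loci. Re-watered midday replicate 3 had the lowest mean correlation with its own group (0.962), and day 0 midnight replicate 3 was next (0.963). In re-watered midday replicate 3 the 10 most abundant loci held 12.6% of the counts, compared with 23.5% and 20.3% in the other two. LHCB3, a light-harvesting protein, stood at 3120 CPM in it, compared with 9597 and 8396. Among the day 0 midnight libraries LHCB3 ranged from 23.5 to 196.5. No 2 libraries were identical.

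**Figure D1:**
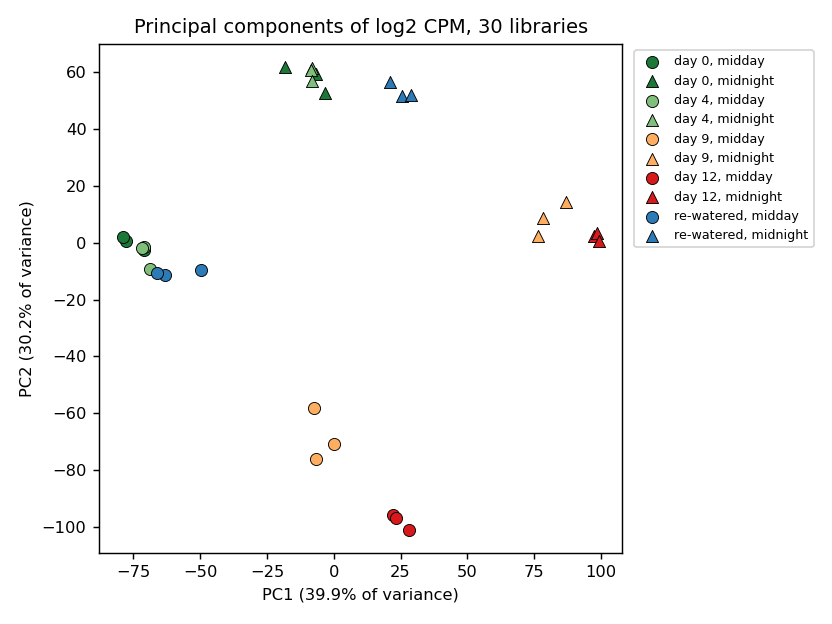
Principal components of the log2 CPM of the 30 libraries, one point per library, with component 1 (39.9% of the variance) on the horizontal axis and component 2 (30.2%) on the vertical axis. Colours mark the water stage and shapes the time of day.

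To find the earliest response, leaves after 4 days without water were compared with leaves at day 0. Little change was detected. At midnight LBD39 (AT4G37540), a transcription factor of the LOB family, rose by 2.34 ± 0.42 (adjusted p = 0.0289), the chlorophyll-breakdown gene PPH fell (-1.34 ± 0.28, adjusted p = 0.038) and the beta-amylase BAM1 fell (-1.32 ± 0.27, adjusted p = 0.038). A reversibly glycosylated polypeptide (AT3G02230), of a family that acts in cell wall synthesis, fell as well (-1.4 ± 0.25, adjusted p = 0.0289). In all, 26 loci changed at midnight, 7 upwards and 19 downwards, and the authors' deposited table lists 51 (16 higher and 35 lower) at a q-value under 0.01. Without day 0 midnight replicate 1 the adjusted p was 0.158 for AT4G37540, 0.236 for PPH, 0.228 for BAM1 and 0.091 for AT3G02230. Without day 0 midnight replicate 2 or single day 4 libraries these calls were mostly lost too (for PPH, adjusted p = 0.0756 without day 0 replicate 2 and 0.177, 0.128 and 0.103 without day 4 midnight replicates 1, 2 and 3). The count ranged from 0 without day 0 midnight replicate 1 to 672 without day 0 midnight replicate 3. At midnight DESeq2 called 235 loci and limma-trend called 50. At midday edgeR called 0 loci. At an unadjusted p under 0.05 there were 1052 against 703 by chance, DESeq2 called 0 and limma-trend called 0, and the authors' deposited table also lists 0 at a q-value under 0.01. None of the 21 gene lists passed at midday (smallest adjusted p = 0.343). At midnight only the photosystem and light-harvesting list did, with a median log2 change of 0.40 over 30 members of which no single one was called (adjusted p = 0.000359, and adjusted p = 0.584 with an estimated correlation). Guard cell markers (adjusted p = 0.176) and vascular markers (adjusted p = 0.317) did not pass at midnight.

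The comparison of day 9 with day 0 asks what changes once the leaves are in the CAM mode, first at midday, when malate is decarboxylated. Transcripts for malate decarboxylation and transport rose. The malic enzyme NADP-ME1 (AT2G19900) rose from 119 ± 29.5 to 462 ± 7.71 CPM (1.96 ± 0.19, adjusted p = 4.03e-09), NADP-ME2 (AT5G11670) by 1.88 ± 0.18 and NADP-ME4 (AT1G79750) by 1.79 ± 0.17. The dicarboxylate carriers DIC1 (AT2G22500) and DIC2 (AT4G24570) showed the largest changes of the CAM list, with DIC1 at 848 ± 42.9 compared with 66.8 ± 15.4 (3.67 ± 0.36, adjusted p = 1.31e-08) and DIC2 up by 3.44 ± 0.39. Pyruvate orthophosphate dikinase, PPDK (AT4G15530), which returns pyruvate to phosphoenolpyruvate, rose by 2.03 ± 0.38. The carboxylase loci PPC1 (AT1G53310) and PPC2 (AT2G42600) were already higher at midday, at 1805 ± 125 compared with 414 ± 232 for PPC1 (2.13 ± 0.31, adjusted p = 3.4e-06) and by 2.22 ± 0.28 for PPC2. Contigs given for PPC1 in the authors' deposited contig table were higher at midday as well, with log2 changes of 3.83 and 3.69. Those for PPC2 were not listed at a q-value under 0.01 (0.56, DESeq2 q = 0.186, and 0.75, q = 0.596). The rise of the PPC2 locus at midday is therefore uncertain. The carboxylase kinases PPCK1 (1.58 ± 0.23) and PPCK2 (1.55 ± 0.29), the carbonic anhydrases BCA5 (0.72 ± 0.17) and BCA6 (1.09 ± 0.23), and the malate dehydrogenases NADP-MDH (0.84 ± 0.16) and plNAD-MDH (0.74 ± 0.21) also rose. The phosphoenolpyruvate translocator PPT2 (-1.27 ± 0.17) and the aminotransferase ASP1 (-0.78 ± 0.18) fell. Of the 36 measured members of the C4-acid and CAM list, 15 rose and 2 fell, the same numbers as when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.00541, and adjusted p = 0.135 with an estimated correlation).

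**Figure D2:**
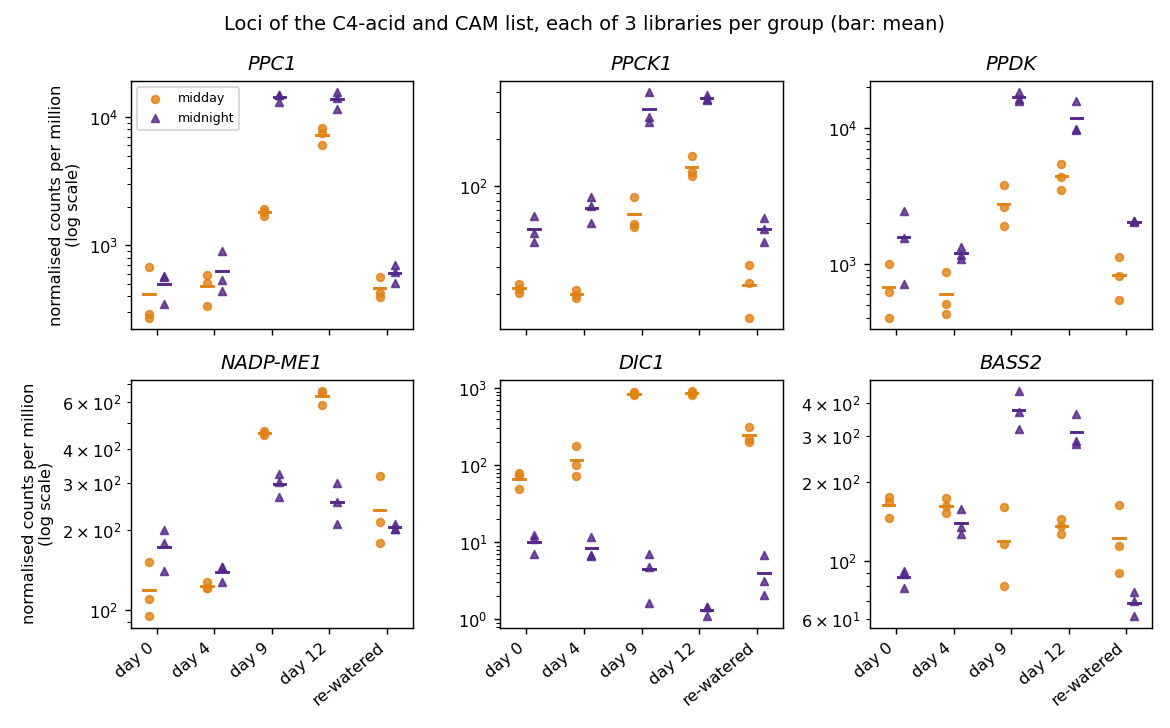
Normalised CPM (log scale) of loci of the C4-acid and CAM list in each library over the 5 water stages, with midday as circles, midnight as triangles and a bar at the mean of 3 libraries. PPC1 at midnight rises from 495 at day 0 to 14250 at day 9 and stands at 613 after re-watering.

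Transcripts of starch turnover and glycolysis genes rose alongside at midday on day 9. The glucan, water dikinase GWD1, which phosphorylates starch for breakdown, rose by 2.26 ± 0.26 (adjusted p = 8.44e-08), the beta-amylase BAM2 by 1.86 ± 0.20, the limit dextrinase LDA by 1.6 ± 0.22 and the disproportionating enzyme DPE1 by 1.13 ± 0.15. In the starch degradation list 14 of 20 members rose, also when adjusted over the list alone, with a median of 1.3 (adjusted p = 4.59e-05, and adjusted p = 0.278 with an estimated correlation). Starch synthesis genes were higher as well, with 8 of 15 up and 2 down (9 and 3 when adjusted over the list alone; median 0.45, adjusted p = 0.0146, and adjusted p = 0.334 with an estimated correlation). Among them the starch synthase SS1 rose by 3.12 ± 0.35 and the pyrophosphorylase subunits APL2 by 1.94 ± 0.26 and APL4 by 2.42 ± 0.37. The glycolysis list had 10 of 17 members up and 2 down (11 and 2 when adjusted over the list alone; median 0.78, adjusted p = 0.00442, and adjusted p = 0.278 with an estimated correlation), led by the aldolase FBA5 (2.38 ± 0.23), the enolase ENO2 (1.61 ± 0.23) and the phosphoglycerate mutases IPGAM1 (1.15 ± 0.15) and IPGAM2 (1.23 ± 0.17).

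Photosynthetic transcripts were lower at midday on day 9. The photosystem I subunits PSAF (-1.69 ± 0.30, adjusted p = 4.81e-05), PSAK (-1.42 ± 0.27), PSAN (-1.77 ± 0.34) and PSAO (-1.50 ± 0.35) led the photosystem and light-harvesting list, in which 17 of 30 members fell (18 when adjusted over the list alone; median -0.81, adjusted p = 0.000495, and adjusted p = 0.571 with an estimated correlation). In the Calvin-Benson list 7 of 17 fell and 1 rose, and the list did not pass (median -0.55, adjusted p = 0.161). RBCS1A, a small subunit of Rubisco, fell from 77730 ± 25690 to 35580 ± 1683 (-1.13 ± 0.32, adjusted p = 0.00557), GAPB fell by 0.93 ± 0.26 and SBPASE rose by 0.96 ± 0.19. Photorespiration genes moved in both directions, with GLDP2 (1.46 ± 0.25) and SHM1 (0.97 ± 0.17) up and PGLP1 (-0.92 ± 0.22) down (4 up and 3 down of 14, adjusted p = 0.867).

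Genes of osmotic protection, water transport and growth changed strongly at midday on day 9. In the drought marker list 10 of 14 members rose and 1 fell (10 and 2 when adjusted over the list alone; median 1.94, adjusted p = 0.00118, and adjusted p = 0.28 with an estimated correlation). P5CS1, of proline synthesis, rose from 213 ± 8.62 to 1419 ± 353 (2.73 ± 0.22, adjusted p = 1.66e-10), the homeobox factor ATHB7 by 3.03 ± 0.30, the dehydrin COR47 by 3.17 ± 0.36 and the galactinol synthase GOLS1 by 3.17 ± 0.35. Aquaporins fell, with 8 of 10 down, also when adjusted over the list alone (median -1.63, adjusted p = 0.00014, and adjusted p = 0.28 with an estimated correlation), among them TIP2;2 (AT4G17340, -4.27 ± 0.73) and PIP2;2 (AT2G37170, -2.37 ± 0.25). Expansins and cell cycle genes also fell, with 8 of 10 down and 1 up, the same when adjusted over the list alone (median -2.61, adjusted p = 8.64e-05, and adjusted p = 0.276 with an estimated correlation). Examples are EXPA4 (-2.77 ± 0.24), EXPA3 (-3.48 ± 0.50) and the cyclin CYCD3;1 (AT4G34160, -2.19 ± 0.34). Heat shock and chaperone genes had 10 of 16 members up and 1 down, the same when adjusted over the list alone (median 1.11, adjusted p = 0.00232, and adjusted p = 0.278 with an estimated correlation), with HSP21 up by 4.71 ± 0.33, HSP22 by 5.26 ± 0.61 and BAG6 by 4.15 ± 0.44.

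Other lists did not pass at midday on day 9, although single members did. In abscisic acid signalling 7 of 17 rose and 4 fell (adjusted p = 0.61), with a median of 0.30 and a mean of -0.18. The receptors PYR1 (-2.53 ± 0.23) and PYL4 (-3.82 ± 0.40) fell and the phosphatases HAI1 (2.76 ± 0.39) and HAI2 (1.45 ± 0.27) rose. In abscisic acid synthesis and turnover 3 of 11 rose and 2 fell (adjusted p = 0.61), among them the hydroxylases CYP707A2 (-2.11 ± 0.31) and CYP707A1 (1.71 ± 0.29). The clock list had 10 of 24 up and 6 down (adjusted p = 0.382), with RVE6 (1.08 ± 0.14), LNK1 (1.2 ± 0.18) and TOC1 (1.2 ± 0.23) up and CDF3 (-0.92 ± 0.17) down. Adjusted p was 0.0642 for senescence and chlorophyll breakdown (5 up and 1 down of 12), 0.951 for wax and cuticle (4 and 4 of 13), 0.242 for antioxidant enzymes (1 and 5 of 11), 0.61 for vacuolar proton pumps (3 and 2 of 13) and 0.867 for nitrogen assimilation (3 up of 10, with a list median of -0.33). Within these lists the wax-related LACS2 fell by 2.08 ± 0.18, SAG29 rose by 1.57 ± 0.19, SGR2 rose by 3.19 ± 0.51 and the proton pyrophosphatase AVP1 fell by 1.38 ± 0.31. Markers of other leaf cell types moved too. In the guard cell list ALMT12 (-2.07 ± 0.31), MYB60 (-1.25 ± 0.26) and HT1 (-0.79 ± 0.22) fell and the potassium channel GORK rose (2.12 ± 0.38), 1 up and 4 down of 6 (adjusted p = 0.161). In the vascular list the cellulose synthases IRX5 (-1.4 ± 0.14), IRX3 (-1.17 ± 0.14) and IRX1 (-0.94 ± 0.17) fell and the sucrose exporter SWEET11 rose (2.23 ± 0.21), 1 up and 4 down of 9 (adjusted p = 0.146). The epidermis and defence lists had fewer than 3 measured members and were not tested, and the defence gene LOX2 rose by 1.38 ± 0.39 (adjusted p = 0.00545).

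Among the largest increases at midday on day 9 were those of 3 myo-inositol oxygenases. MIOX1 (AT1G14520) rose from 4.69 ± 0.798 to 602 ± 504 (7.0 ± 0.68), MIOX4 (AT4G26260) by 7.52 ± 0.75 and MIOX2 (AT2G19800) by 6.55 ± 0.71. These enzymes open the inositol ring on the way to cell wall sugars. An early light-induced protein (AT3G22840), of a family induced under light stress, rose from 22.2 ± 10.2 to 2853 ± 8.16 (7.0 ± 0.70). Expansin-like B1 (AT4G17030) had no count at day 0 and was at least 63.8-fold higher, with the bound set at 3 counts over the group. The largest decreases were those of germin 3 (AT5G20630), from 3240 ± 1083 to 44.5 ± 31.1 (-6.18 ± 0.69), and germin-like protein 1 (AT1G72610, -6.07 ± 0.70), both extracellular proteins. An endoglucanase-type hydrolase (AT1G64390, -5.18 ± 0.45), an extensin-like protein (AT1G12090, -4.80 ± 0.38), the replication helicase subunit AT5G46280 (-5.01 ± 0.62) and a DNA primase (AT5G41880, -4.93 ± 0.48) also fell. In total 6247 loci changed, 3291 upwards and 2956 downwards, which is 44.5% of those tested. The larger side depended on the scaling, with 2688 upwards and 3476 downwards under upper quartile scaling, 2959 and 3267 under RLE and 2935 and 3223 with DESeq2. The authors' deposited table lists 4628 at a q-value under 0.01.

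At midnight on day 9, when malate is formed, the carboxylation genes changed most within the CAM list. PPC1 rose from 495 ± 127 to 14250 ± 992 CPM (4.85 ± 0.35, adjusted p = 1.75e-11) and PPC2 from 303 ± 74.6 to 9201 ± 692 (4.92 ± 0.32, adjusted p = 2.41e-12). PPDK rose from 1577 ± 873 to 16880 ± 1290 (3.42 ± 0.40), PPCK1 by 2.57 ± 0.23, PPCK2 by 2.14 ± 0.25 and the plastid pyruvate transporter BASS2 (AT2G26900) by 2.13 ± 0.20. The translocators PPT2 (-3.02 ± 0.21) and PPT1 (-1.21 ± 0.17) and the aminotransferase ASP1 (-1.23 ± 0.18) fell. The malic enzymes NADP-ME1, NADP-ME2 and NADP-ME4 were higher by 0.78 ± 0.18, 0.79 ± 0.17 and 0.86 ± 0.16. DIC1 was lower (-1.16 ± 0.40, adjusted p = 0.0194), a call that was lost without day 0 midnight replicate 1 (adjusted p = 0.0627) or 2 (adjusted p = 0.0509) or day 9 midnight replicate 2 (adjusted p = 0.0839). Contigs given for DIC1 in the authors' deposited contig table disagreed at midnight. They went from 7.33 to 8.33 RPM (DESeq2 q = 0.733) and from 25.7 to 4.67 (q = 5.42e-05). Of the 36 members 11 rose and 7 fell (11 and 8 when adjusted over the list alone). The list as a whole did not pass (median -0.09, mean 0.48, adjusted p = 0.299).

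Starch breakdown genes fell at midnight on day 9, with 11 of 20 members down and 1 up (12 and 2 when adjusted over the list alone; median -0.79, adjusted p = 0.0486, and adjusted p = 0.769 with an estimated correlation). The maltose exporter MEX1 fell from 84.9 ± 30.5 to 20.6 ± 2.96 (-2.04 ± 0.19, adjusted p = 2.36e-09), the phosphoglucan phosphatase SEX4 by 1.77 ± 0.24 and the dikinase PWD by 1.29 ± 0.22. Abscisic acid signalling had 11 of 17 members up and 4 down, the same when adjusted over the list alone (median 1.15, adjusted p = 0.0042, and adjusted p = 0.769 with an estimated correlation), with the kinases OST1 (1.15 ± 0.14) and SNRK2.2 (1.12 ± 0.15) and the phosphatases HAI1 (2.52 ± 0.34) and HAI2 (2.02 ± 0.26) up. Aquaporins had 7 of 10 members down (median -0.99, adjusted p = 0.0042, and adjusted p = 0.769 with an estimated correlation), among them TIP1;1 (AT2G36830, -2.79 ± 0.36). Antioxidant enzymes had 8 of 11 down (median -1.2, adjusted p = 0.0042, and adjusted p = 0.632 with an estimated correlation), among them the glutathione reductase GR1 (-1.64 ± 0.13) and the superoxide dismutases CSD1 (-1.69 ± 0.16) and MSD1 (-0.98 ± 0.14). Vascular markers fell beside them, with 6 of 9 down and 1 up (median -0.73, adjusted p = 0.0314, and adjusted p = 0.632 with an estimated correlation), and the cellulose synthases IRX5 (-1.86 ± 0.14), IRX3 (-1.75 ± 0.14) and IRX1 (-1.89 ± 0.18) led them. Guard cell markers did not pass (adjusted p = 0.947), with GORK up by 3.25 ± 0.32 and HT1 down by 0.75 ± 0.20.

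Single members of other lists, whose tests at midnight are not given here, changed as well on day 9. The phosphofructokinases PFK1 (3.76 ± 0.25), PFK3 (3.69 ± 0.22) and PFK4 (4.1 ± 0.26) rose at midnight, and PFK5 fell (-0.90 ± 0.14). The nitrate reductases NIA1 (-4.33 ± 0.80) and NIA2 (-4.23 ± 0.79), the pheophytinase PPH (-3.16 ± 0.31) and the wax gene CER4 (-6.01 ± 0.52) fell. A protein of the phosphatidylethanolamine-binding family (AT1G18100) rose from 0.589 ± 0.573 to 51.3 ± 7.11 (6.36 ± 0.58), and AT3G27250, without annotation, rose by 5.67 ± 0.36. The largest decreases were again those of the germins AT1G72610 (-8.62 ± 0.90) and AT5G20630 (-8.52 ± 0.82). Other large ones were those of the lipases AT4G28780 (-6.89 ± 0.82) and AT5G33370 (-6.82 ± 0.79) and laccase 17 (AT5G60020, -6.45 ± 0.53), an enzyme of lignin polymerisation. In total 6833 loci changed, 3261 upwards and 3572 downwards, and the authors' deposited table lists 5191 at a q-value under 0.01.

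**Figure D3:**
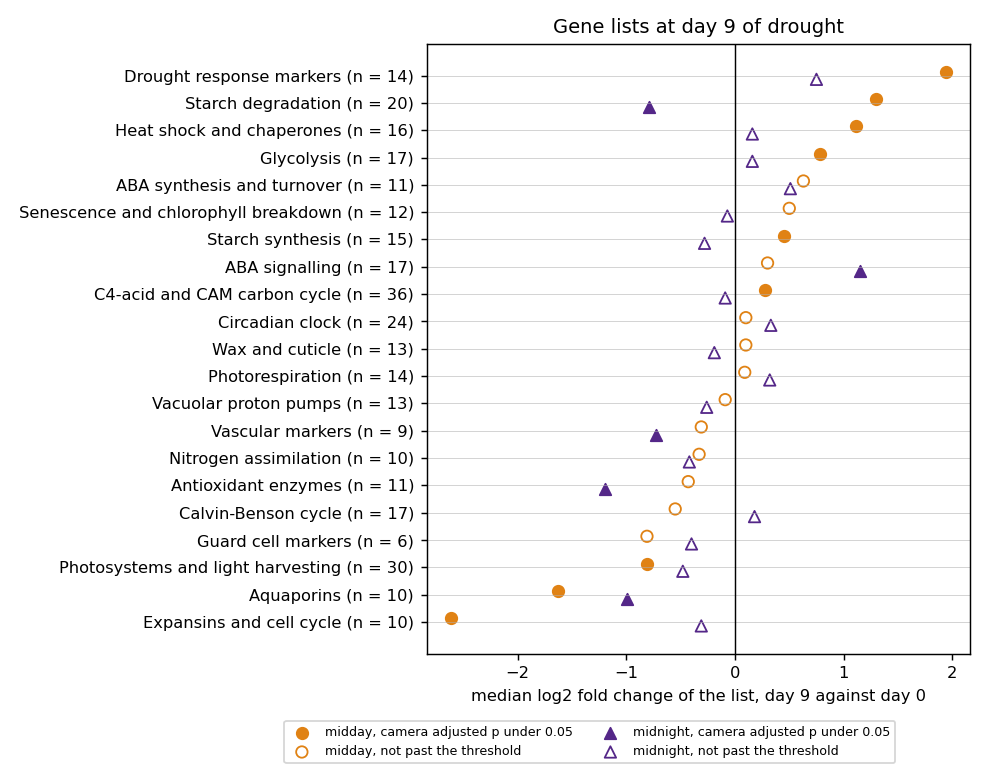
Median log2 fold change of each tested gene list at day 9 against day 0, at midday (circles) and midnight (triangles), with the number of measured members after each name. Filled symbols passed the camera test with a preset correlation, and none passed with an estimated correlation. Starch degradation lies at 1.3 at midday and -0.79 at midnight.

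The day 12 comparison asks whether the response grows with 3 more days of drought. At midday the carboxylases rose, with PPC1 at 7257 ± 1057 (4.13 ± 0.34 against day 0, adjusted p = 9.46e-11) and PPC2 at 5237 ± 765 (4.25 ± 0.31). NADP-ME1 stood at 634 ± 41.3 (2.41 ± 0.19), DIC1 at 862 ± 59.3 (3.69 ± 0.36) and PPDK at 4443 ± 999 (2.72 ± 0.39). The tonoplast dicarboxylate transporter TDT had no count at day 0 and was at least 33.6-fold higher at midday and at least 76.9-fold higher at midnight, with the same bound as above. The CAM list had 17 of 36 members up and 7 down, the same when adjusted over the list alone (median 0.40, adjusted p = 0.014, and adjusted p = 0.235 with an estimated correlation). The difference between day 12 and day 9 was not tested. Contigs given for PPC1 in the authors' deposited contig table stood at 65.7 and 10 RPM at midday on day 9. On day 12 they stood at 63.3 and 12. These values do not show the further rise seen at the PPC1 locus. Those for PPC2 went from 492 to 856 and from 0 to 1.

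At midday on day 12 the other lists that had passed on day 9 passed again, except heat shock. Photosystem genes had 23 of 30 down (median -1.16, adjusted p = 3.69e-05, and adjusted p = 0.435 with an estimated correlation), with PSAN at -2.84 ± 0.36. Starch degradation had 16 of 20 up (median 1.2, adjusted p = 3.69e-05, and adjusted p = 0.359 with an estimated correlation), with GWD1 at 3.08 ± 0.27. Starch synthesis had 10 of 15 up and 3 down (adjusted p = 0.0198, and adjusted p = 0.4 with an estimated correlation), with SS1 at 4.73 ± 0.37, and glycolysis 11 of 17 up and 1 down (adjusted p = 0.0113, and adjusted p = 0.359 with an estimated correlation). Drought markers had 10 of 14 up and 4 down (median 2.38, adjusted p = 0.0041, and adjusted p = 0.391 with an estimated correlation), with COR47 at 4.39 ± 0.35. Aquaporins had 8 of 10 down (median -2.01, adjusted p = 6.44e-05, and adjusted p = 0.359 with an estimated correlation) and expansins and cell cycle 9 of 10 down (median -4.01, adjusted p = 3.69e-05, and adjusted p = 0.248 with an estimated correlation), with EXPA4 at -4.66 ± 0.29. Antioxidant enzymes passed at midday on this day, with 7 of 11 down (median -0.73, adjusted p = 0.0455, and adjusted p = 0.4 with an estimated correlation). Counts adjusted over the list alone were the same or differed by 1 for starch degradation, which had 17 up. Guard cell (adjusted p = 0.142) and vascular markers (adjusted p = 0.154) did not pass. The germins AT5G20630 and AT1G72610 fell by 10.52 ± 0.87 and 10.20 ± 0.91, to 2.19 ± 0.31 and 1.03 ± 0.261 CPM, and MIOX1 (AT1G14520) reached 1404 ± 306 (8.22 ± 0.71).

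At midnight on day 12 PPC1 stood at 13670 ± 2074 (4.79 ± 0.35) and PPC2 at 8733 ± 1247 (4.85 ± 0.32), PPCK1 at 367 ± 15 compared with 52.5 ± 10.6 (2.80 ± 0.23), and BASS2 was higher by 1.84 ± 0.20. DIC1 fell to 1.32 ± 0.201 compared with 10 ± 2.78 (-2.91 ± 0.47), and PPT2 (-3.16 ± 0.21), PPT1 (-1.88 ± 0.17) and the aminotransferases ASP1 (-1.72 ± 0.18) and ASP5 (-1.4 ± 0.19) fell. The CAM list did not pass (13 up and 12 down, adjusted p = 0.71). Photosystem genes (15 of 30 down, median -0.68, adjusted p = 0.00486), starch degradation (12 of 20 down and 2 up, median -1.01, adjusted p = 0.0282), vacuolar proton pumps (10 of 13 down, median -0.41, adjusted p = 0.00877), antioxidant enzymes (9 of 11 down, median -1.54, adjusted p = 0.000527) and vascular markers (5 of 9 down and 1 up, median -0.73, adjusted p = 0.0304) were lower, and abscisic acid signalling was higher (11 of 17 up and 4 down, median 1.49, adjusted p = 0.00462). With an estimated correlation these 6 gave adjusted p = 0.811, adjusted p = 0.811, adjusted p = 0.75, adjusted p = 0.402, adjusted p = 0.402 and adjusted p = 0.75 in the same order. Adjusted over the list alone, starch degradation had 3 up, antioxidant enzymes 10 down and vascular markers 6 down, and the other counts were the same. Examples are the amylase AMY3 (2.08 ± 0.19), which rose against its list, the pump subunits VHA-F (-1.14 ± 0.14) and VHA-D (-0.92 ± 0.12), CSD1 (-2.51 ± 0.17) and the kinase OST1 (1.51 ± 0.14). Guard cell markers did not pass (adjusted p = 0.881). In all 7732 loci changed at midday, 4117 upwards and 3615 downwards, and 8091 at midnight, 3904 upwards and 4187 downwards. At midday the larger side turned under other scalings, with 3322 upwards and 4195 downwards under upper quartile scaling, 3517 and 4061 under RLE and 3461 and 4026 with DESeq2.

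The calls of day 9 and day 12 overlapped. At midday 2852 loci were higher and 2619 lower on both days, against 964 and 760 for independent lists of these sizes, and 11 were called in opposite directions. At midnight 2738 were higher and 3147 lower on both days, against 906 and 1064. The fold changes correlated across loci at r = 0.89 at midday (covariance 1.4) and r = 0.91 at midnight (covariance 1.38). Unchanged groups simulated against the same day 0 libraries gave r = 0.51 and r = 0.50, covariances of 0.06 and 0.05, and no shared calls in 20 draws. Hardly any locus is called where nothing changes. The lack of shared calls therefore cannot show how much the shared libraries add to the overlap. Loci are not independent replicates, and part of the excess may come from the shared day 0 libraries. Midday and midnight of day 9, which share no library, had 3319 calls in the same direction (1492 higher and 1827 lower, against 764 and 751) and 412 in opposite directions.

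**Figure D4:**
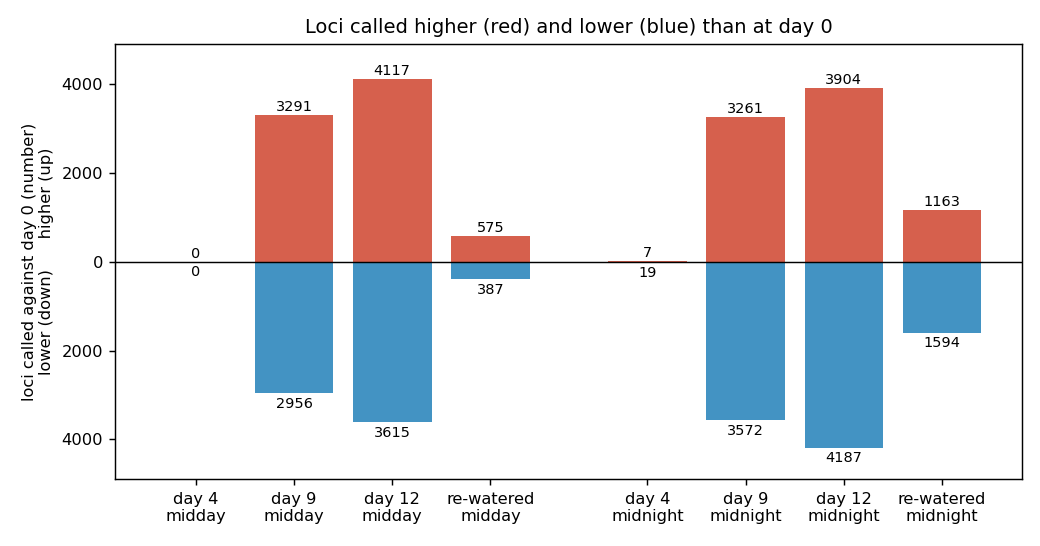
Number of loci called higher (red, upwards) and lower (blue, downwards) than at day 0 for each stage and time of day. The bars reach 4117 and 3615 at midday on day 12 and are 575 and 387 at midday after re-watering, and with upper quartile scaling the lower side is the larger one in both.

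How day and night differ within a stage was tested as midnight against midday. In well-watered leaves the light-harvesting genes were far lower at midnight. LHCB3 stood at 91.2 ± 92.4 compared with 10780 ± 2262 (-6.88 ± 0.85, adjusted p = 7.55e-07), LHCB6 was at -6.82 ± 0.71 and LHCA4 at -6.67 ± 0.82, and 27 of 30 members of the photosystem list were lower (28 when adjusted over the list alone; median -3.38, adjusted p = 7.94e-26, and adjusted p = 0.239 with an estimated correlation). Urease (AT1G67550) was higher at midnight, at 154 ± 24.4 compared with 3.49 ± 1.02 (5.45 ± 0.35), as was AT2G38905 of a salt- and cold-responsive family (5.63 ± 0.52). The clock genes PRR9 (-6.75 ± 0.35) and PRR3 (-6.61 ± 0.40) were lower at midnight on day 4. On day 9 the photosystem list was again lower at midnight (27 of 30, median -2.67, adjusted p = 1.92e-16, and adjusted p = 0.152 with an estimated correlation), and the CAM list had 22 of 36 members lower and 8 higher (median -0.54, adjusted p = 0.0164, and adjusted p = 0.152 with an estimated correlation). Expansins were among the loci most raised at midnight on day 9, with expansin A14 (AT5G56320) at 6.08 ± 0.63 and EXPA10 at 4.71 ± 0.61. On day 12 the dicarboxylate carriers AT5G09470 (-9.88 ± 0.40) and DIC1 (-9.33 ± 0.50) were lower at midnight. Counts of loci that differed between midnight and midday were 6175 on day 0, 5885 on day 4, 6960 on day 9, 7686 on day 12 and 6618 after re-watering.

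Whether drought acted differently by day and by night was tested as an interaction, the log2 change from day 0 at midnight minus that at midday. On day 9 PPC1 (2.72 ± 0.43, adjusted p = 4.84e-05), PPC2 (2.70 ± 0.39) and BASS2 (2.58 ± 0.28) responded more at midnight, and DIC1 (-4.83 ± 0.53, adjusted p = 5.53e-07), NADP-ME1 (-1.18 ± 0.25) and NADP-ME2 (-1.1 ± 0.24) more at midday. The starch degradation list gave the clearest difference, with 16 of 20 members negative (19 negative and 1 positive when adjusted over the list alone; median -1.50, adjusted p = 2.3e-11, and adjusted p = 0.135 with an estimated correlation), and MEX1 (-2.73 ± 0.26), SEX4 (-2.87 ± 0.33), BAM2 (-2.38 ± 0.28) and ISA3 (-2.67 ± 0.32) led it. P5CS1 (-3.55 ± 0.30), raised at midday, was lower at midnight (-0.82 ± 0.21, adjusted p = 0.00204). Expansins and cell cycle genes, whose median change was -2.61 at midday, had 6 of 10 members positive and 1 negative, the positive sign meaning a less negative or a positive value at midnight (median 2.02, adjusted p = 0.00411, and adjusted p = 0.33 with an estimated correlation), with EXPA8 at 5.08 ± 0.89. The vascular marker SWEET11 differed as well (-1.42 ± 0.28). In all 3410 loci showed an interaction on day 9 and 4754 on day 12. On day 12 PPC1 (0.65 ± 0.42, adjusted p = 0.243) and PPC2 (0.60, adjusted p = 0.237) were not called in the locus counts, whereas starch degradation (18 of 20 negative and 1 positive, median -1.73, adjusted p = 2.13e-10, and adjusted p = 0.182 with an estimated correlation), DIC1 (-6.60 ± 0.58) and BASS2 (2.11 ± 0.28) differed. In the authors' deposited contig table, contigs given for PPC1 went from 4 to 63.3 and from 0.333 to 12 RPM at midday. At midnight they went from 66.3 to 6460 and from 10.7 to 1200. The difference was not tested on contigs, so the locus result does not show that it was gone.

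**Figure D5:**
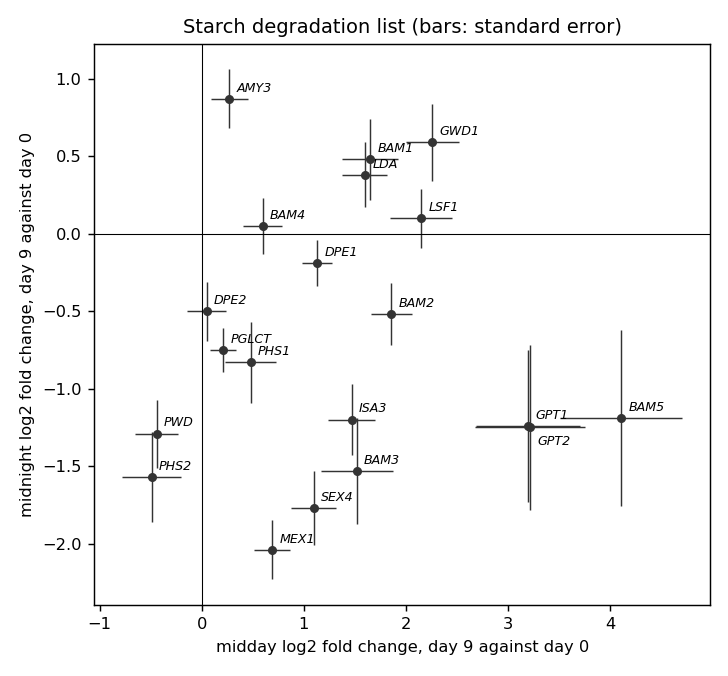
Log2 fold change from day 0 to day 9 of the 20 members of the starch degradation list at midday (horizontal axis) and midnight (vertical axis), with standard errors as bars. MEX1 lies at -2.04 at midnight, and GWD1 at 2.26 at midday.

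Re-watering was compared with day 12 to ask which changes are reversed within 2 days. The carboxylases dropped back, PPC1 to 461 ± 93.7 at midday (-3.98 ± 0.33) and 613 ± 96.7 at midnight (-4.48 ± 0.34) and PPC2 likewise (-4.21 ± 0.31 and -4.67 ± 0.31). PPCK1 (-2.54 ± 0.23 at midday, -2.80 ± 0.23 at midnight) and PPDK (-2.43 ± 0.38 and -2.53 ± 0.38) fell at both times, NADP-ME1 (-1.42) and DIC1 (-1.82 ± 0.33) fell at midday, and PPT2 rose (1.29 ± 0.18 and 1.92 ± 0.21). At midday the CAM list had 15 of 36 down and 6 up (17 and 6 when adjusted over the list alone; adjusted p = 0.0137, and adjusted p = 0.208 with an estimated correlation). Expansins and cell cycle genes had 9 of 10 up and 1 down (median 3.24, adjusted p = 0.00099, and adjusted p = 0.392 with an estimated correlation), aquaporins 8 of 10 up (median 1.36, adjusted p = 0.00151, and adjusted p = 0.507 with an estimated correlation) and photosystem genes 16 of 30 up and 1 down (median 0.79, adjusted p = 0.011, and adjusted p = 0.645 with an estimated correlation). Drought markers had 10 of 14 down and 4 up (median -1.69, adjusted p = 0.0155, and adjusted p = 0.507 with an estimated correlation), starch degradation 13 of 20 down and 2 up (median -0.67, adjusted p = 0.00611, and adjusted p = 0.507 with an estimated correlation) and glycolysis 8 of 17 down and 1 up (adjusted p = 0.00635, and adjusted p = 0.392 with an estimated correlation). The counts of these 6 were the same when adjusted over the list alone. Germin 3 (AT5G20630) returned to 1414 ± 915 (9.32 ± 0.84), the early light-induced protein (AT3G22840) fell from 4426 ± 793 to 29.2 ± 22.0 (-7.23 ± 0.71) and MIOX1 (AT1G14520) fell by 6.50 ± 0.64. In all 6702 loci changed at midday and 6027 at midnight.

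At midnight re-watering lowered abscisic acid signalling (12 of 17 down and 3 up, 12 and 4 when adjusted over the list alone; median -1.51, adjusted p = 0.000723, and adjusted p = 0.49 with an estimated correlation) and drought markers (8 of 14 down and 2 up, 9 and 2 when adjusted over the list alone; adjusted p = 0.0404, and adjusted p = 0.91 with an estimated correlation). It raised antioxidant enzymes (6 of 11, 7 when adjusted over the list alone; median 0.93, adjusted p = 0.00235, and adjusted p = 0.469 with an estimated correlation). Vascular markers rose beside them (6 of 9 up and 1 down, median 0.94, adjusted p = 0.0177, and adjusted p = 0.398 with an estimated correlation). The flavonoid gene dihydroflavonol reductase (AT5G42800) rose from 0.349 ± 0.148 to 67.1 ± 23.5 (7.55 ± 0.99). Of the loci raised at midday on day 12, 2871 fell on re-watering, and 2689 of the lowered ones rose, against 1020 and 828 for independent lists. At midnight these were 2394 and 2693, against 805 and 933. The comparisons share the day 12 libraries, so part of the excess may come from them. Simulated unchanged groups gave r = -0.51 at midday, beside the observed r = -0.93 across loci, with covariances of -0.06 and -1.79.

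Re-watered leaves were compared with day 0 to ask how they differed. The plants were also older than at day 0, and no watered plants of that age were sampled. At midday PPC1 (461 ± 93.7 compared with 414 ± 232, 0.16 ± 0.30, adjusted p = 0.786), PPC2 (0.04), PPDK (0.29) and PPCK1 (0.06) did not differ by the test. NADP-ME1 was still higher at 237 ± 71.5 (0.99 ± 0.18, adjusted p = 0.00251), as was DIC1 at 244 ± 63.3 (1.87 ± 0.34, adjusted p = 0.00251). CYP87A2 (AT1G12740), a cytochrome P450, was higher by 6.22 ± 1.02 (adjusted p = 0.00131). The polyketide cyclase family protein AT1G23130 was lower (-2.36 ± 0.31, adjusted p = 0.000135). Starch degradation genes were higher, with 6 of 20 up (10 when adjusted over the list alone; median 0.46, adjusted p = 0.000117, and adjusted p = 0.508 with an estimated correlation), but the calls of GPT1 (2.55 ± 0.50), GPT2 (2.52 ± 0.53) and BAM5 (2.50 ± 0.57) were lost without re-watered midday replicate 3 (adjusted p = 0.0605, 0.0976 and 0.0882). Those of GPT2 (adjusted p = 0.0532) and BAM5 (adjusted p = 0.0851) were also lost without day 0 midday replicate 1, and that of BAM5 (adjusted p = 0.05) without re-watered midday replicate 2. Photosystem genes were lower (1 of 30 called, median -0.43, adjusted p = 6.84e-06, and adjusted p = 0.508 with an estimated correlation), and that same library had the low LHCB3 value given above. Aquaporins (1 of 10 down, 3 when adjusted over the list alone; median -0.53, adjusted p = 0.00158, and adjusted p = 0.508 with an estimated correlation) and drought markers (2 of 14 up, 3 when adjusted over the list alone; median 0.40, adjusted p = 0.00721, and adjusted p = 0.508 with an estimated correlation) passed too. Guard cell and vascular markers did not (adjusted p = 0.84 for each). In all 962 loci differed, 575 upwards and 387 downwards, which is 59.8% higher. The split was 499 and 534 with upper quartile scaling and 597 and 650 with DESeq2. The count was 138 without re-watered midday replicate 3 and 1975 without replicate 1, and edgeR called 0 when only these groups entered the fit, which ended the calls named here.

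At midnight re-watered leaves differed from day 0 at 2757 loci, 1163 upwards and 1594 downwards. Light-harvesting genes were lower, with LHCA1 at -4.00 ± 0.45, LHCA3 at -3.26 ± 0.44 and LHCB5 at -2.96 ± 0.40, and 12 of 30 photosystem genes were down, as when adjusted over the list alone (median -0.48, adjusted p = 2.88e-07, and adjusted p = 0.502 with an estimated correlation). Starch degradation genes were lower, with 11 of 20 down (13 when adjusted over the list alone; median -0.77, adjusted p = 2.54e-07, and adjusted p = 0.234 with an estimated correlation), among them MEX1 (-1.66 ± 0.19) and SEX4 (-1.79 ± 0.24). Vacuolar proton pumps had 9 of 13 down (11 when adjusted over the list alone; median -0.44, adjusted p = 8.32e-06, and adjusted p = 0.234 with an estimated correlation), with VHA-D at -0.83 ± 0.12. Antioxidant enzymes had 5 of 11 down (median -0.50, adjusted p = 0.00116, and adjusted p = 0.234 with an estimated correlation) and glycolysis 6 of 17 down and 1 up (8 and 1 when adjusted over the list alone; adjusted p = 0.0262, and adjusted p = 0.475 with an estimated correlation). PPT2 (-1.24 ± 0.18), PPT1 (-0.86 ± 0.17) and NAD-ME1 (-0.56 ± 0.12) were lower, whereas PPC1 (0.31 ± 0.30, adjusted p = 0.496), PPDK (0.38, adjusted p = 0.493) and PPCK1 (0.01, adjusted p = 0.987) did not differ by the test. The basic chitinase AT3G12500 stood at 45.1 ± 13.8 compared with 1221 ± 866 (-4.76 ± 0.83). The P450 AT5G48000 was higher by 3.19 ± 0.78, at 27.2 CPM compared with 3.05 at day 0. It had stood at 0.124 on day 12, so its rise came with re-watering. Guard cell (adjusted p = 0.708) and vascular markers (adjusted p = 0.474) did not pass. Of these loci, 858 were higher and 1282 lower at midnight on day 12 as well, against 323 and 475 for independent lists, with r = 0.57 across loci beside a simulated 0.51 and covariances of 0.48 and 0.05. At midday 378 were higher and 283 lower in both, against 168 and 100, and 77 went in opposite directions, with r = 0.46, under the simulated 0.51, and covariances of 0.38 and 0.06. Part of each excess may come from the shared day 0 libraries. The count ranged from 1630 without day 0 midnight replicate 2 to 2812, and was 1359 with only these groups in the fit.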

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

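The tests of shared reads, of exchanged libraries, of the clock, of a mislabelled drought library and the counts over other splits of the libraries were chosen only after the results were seen.

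The response to 9 days of drought differed between midnight and midday at 3410 loci, and that to 12 days at 4754, by a test of the difference itself. With only the groups compared in the fit these were 2367 and 3720. Of 100 splits that exchanged drought and day 0 libraries, 2 gave as many loci as the real split for day 9 and 2 for day 12, the real one included, and the highest other split gave 7052 and 7993. In that one the midday sides changed places, so that the responses were added. The next highest gave 2060 and 2778, below the real values. Such splits remove the drought response as well, so they do not test the interaction alone. By the test itself, in the fit of all groups, 4995 and 6085 loci had an unadjusted p under 0.05, where 703 were expected by chance, and the smallest adjusted p was 1.25e-09 and 2.15e-10. By list, the median interaction on day 9 was 0.79 for the Calvin-Benson cycle, -1.50 for starch degradation, -0.42 for starch synthesis, 0.64 for abscisic acid signalling, -0.70 for senescence and chlorophyll breakdown, 2.02 for expansins and cell cycle, -1.2 for heat shock and chaperones, -0.72 for antioxidant enzymes and -0.79 for wax and cuticle.

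In the CAM list the interaction on day 9 was 2.72 for PPC1, 2.70 for PPC2, 0.99 for PPCK1 and 2.58 for BASS2 (midnight change minus midday change). It was -1.18 for NADP-ME1, -1.1 for NADP-ME2, -0.93 for NADP-ME4, -0.58 for NAD-ME1, -0.53 for NAD-ME2, -1.03 for plNAD-MDH, -1.0 for BCA5, -1.39 for BCA6, -4.83 for DIC1, -4.45 for DIC2, -0.82 for PPT1, -1.75 for PPT2 and -0.89 for ASP5. A negative value stands for a larger rise at midday in some, such as NADP-ME1, and for a larger fall at midnight in others, such as PPT2. Single libraries ended 4 of these calls. Without day 0 midnight replicate 3 the adjusted p was 0.0586 for PPT1, 0.0672 for plNAD-MDH and 0.0553 for NAD-ME2. NAD-ME2 was also lost without day 0 midday replicate 1 (0.057), day 0 midnight replicate 1 (0.0501) and day 9 midday replicate 1 (0.082). PPCK1 was lost without day 0 midday replicate 1 (0.0504), day 0 midnight replicate 1 (0.0642), day 9 midday replicates 2 (0.0613) and 3 (0.0623) and day 9 midnight replicate 2 (0.0875).

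Among the loci with the largest interaction on day 9 were expansin A14 (AT5G56320, 5.97), the P450 AT1G74110 (5.26), the expansin AT5G05290 (5.19), EXPA8 (5.08) and the glutaredoxin AT1G28480 (4.94). In the other direction were the nitrate transporter AT1G32450 (-6.41), the chitinase AT3G12500 (-6.05) and, from very low counts, the transcription factor CBF2 (AT4G25470, -6.20 ± 2.08). The size for CBF2 is poorly known, since it stood at 0.223 CPM at day 0 midday, 0.123 at day 0 midnight and 0.168 at day 9 midnight. Expansin-like B1 (AT4G17030) had no count at day 0 midday, so its fitted interaction (-6.20 ± 2.17) is no measure of size. The call of AT4G25470 was lost without day 0 midnight replicate 1 (adjusted p = 0.0814), 2 (0.0818) or 3 (0.0757). That of AT4G17030 was lost without any one day 0 midday library (0.0702, 0.0618 and 0.0667), day 0 midnight replicates 1 (0.121) and 2 (0.12), day 9 midday replicate 1 (0.0523) and day 9 midnight replicates 1 (0.054) and 3 (0.0553). Among the 3483 contigs without an Arabidopsis match, which the locus table cannot hold, the authors' deposited table lists 213 as higher on day 9 at midday and 239 at midnight at a q-value under 0.01, compared with 0 and 7 on day 4.

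Starch breakdown genes rose at midday and fell at midnight on day 9. The list passed at both times and in the interaction with the preset correlation, and in none of these with an estimated one. The tables argue against a few abundant transcripts as the cause, since the median interaction was -1.49 without the 100 loci of highest count, which held 24.5% to 48.8% of the counts. They argue against exchanged midday and midnight libraries, since 0 of the 12 libraries had PRR9 and TOC1 out of place. Over the 24 clock genes the midnight-to-midday values of day 9 were set against those of day 0. A large shift in the phase of the whole clock would have lowered the slope. The slope was 0.92 (95% interval 0.79 to 1.05), and 19 of the 24 genes kept their sign. With 2 times of day a small shift cannot be excluded. With the preset correlation, the list was also higher at midday and lower at midnight in re-watered leaves against day 0. With an estimated correlation it passed at neither time, and with only the groups compared edgeR called 0 loci at midday. The re-watered leaves had been through 12 days of drought, and these comparisons share the day 0 libraries. They therefore do not show whether the pattern is confined to drought. That drought changed the timing of starch turnover itself stays open as a hypothesis that may account for the pattern, untested with 2 times of day.

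Members of a family rose or fell together, such as PPC1 with PPC2. Reads shared between paralogs may be the cause: in 6 of 6 pairs the log2 ratio varied less over the 30 libraries than in the closest 5% of random pairs (SD of 0.12 for PPC1 and PPC2, against 0.30). In the authors' deposited contig table the contigs given for PPC1 went from 66.3 to 7640 and from 10.7 to 1410 RPM at midnight, and those for PPC2 from 358 to 641 and from 1 to 9.67. The authors' log2 changes were 6.8 and 7 for PPC1, and 0.96 (DESeq2 q = 0.013) and 3.29 for PPC2. The PPC2 locus changed by 4.92, a rise that its more abundant contig did not show at that size. Coordinated change of separate genes was not tested against it.

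The third re-watered midday library stood apart from the other 2. The tables argue against a mislabelled day 9 or day 12 library. PPC1 stood at 392.4 CPM in the third library, compared with a mean of 495.7 in the other 2. Its lowest values were 1680 on day 9 and 6094 on day 12. At midday on day 4 it ranged from 335.9 to 589.4, so a day 4 library is not excluded. The tables also argue against a mix with midnight leaf, which would need a share of 63% for the photosystem values and raise the 100 midnight loci by 1.97, where the median was 0.27 (SE 0.11). A slower recovery of that plant stays open, and no test for it was run.

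The contrasts of 3 libraries with 3 have 10 splits, too few for a share under 0.05. Real value and highest other, with only the groups compared in the fit, were 0 and 200 loci for day 4 at midday and 0 and 0 at midnight, 4757 and 0 for day 9 at midday and 5526 and 0 at midnight, and 6468 and 0 for day 12 at midday and 6284 and 0 at midnight. For re-watering they were 0 and 0 at midday and 1359 and 0 at midnight against day 0, and 5493 and 0 and 6270 and 0 against day 12. For midnight against midday they were 3656, 6243, 7432, 7683 and 6008 for days 0, 4, 9 and 12 and re-watering, each beside 0. Splits with as many loci, the real one included, were 10 of 10 where the real value was 0 and 1 of 10 in the others. The real values of 0 are those of edgeR with only the groups compared. In the fit of all groups day 4 also gave 0 loci at midday, but 26 at midnight. Re-watering against day 0 gave 962 at midday in that fit.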

How the results depend on the processing

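Leaving out both libraries least correlated with their groups was a test chosen only after the data were seen. Counts of calls kept within 1.5 times of the reported ones under RLE scaling, upper quartile scaling and the replicate block in 18 of 18 results each, without a filter in 17 of 17, and no named gene reversed under any alternative run. Named genes kept their side of the threshold in 1188 cases with DESeq2 (11 gained, 1 lost), 1191 with RLE, 1184 with upper quartile scaling, 1185 with limma-trend, 1182 without a filter, 1084 with only the groups compared (111 lost) and 7412 of the cases with 1 library left out (24 gained, 442 lost). For day 4 at midnight (26 loci) DESeq2 called 235, limma-trend 50, the filter of 5 CPM 47, an adjusted p under 0.01 gave 0, at least 2-fold 16, only the groups compared 0, and both libraries left out 1131. For re-watering against day 0 these were 233 at p under 0.01, 376 at 2-fold, 0 with only the groups compared and 224 with both left out at midday, and 1133, 804 and 1359 (only the groups compared) at midnight. At p under 0.01 the interactions gave 1883 and 3141 and the overlap of day 9 calls 2171. At 2-fold, where fewer loci can pass, counts were 2864 and 3098 for day 9 (midday, midnight), 3990 and 3983 for day 12, 3296 and 2682 for re-watering against day 12, 2685, 2598, 3315, 4067 and 2989 for midnight against midday, and 2028 and 3015 for the interactions. Midnight against midday on day 0 gave 3656 with only the groups compared. With an estimated correlation 0 of 126 list calls held. With 1 library left out the ranges were 0 to 672 for day 4 at midnight, 138 to 1975 for re-watering at midday and 1630 to 2812 at midnight. The pseudocount alternative applies to normalised values only and was not run. Apart from fewer libraries or a stricter threshold, the cause was not tested. Depth limits loci under 0.343 to 0.703 CPM.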

Other observations

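The test of annotation families was chosen only after the data were seen. Of 78 families with at least 15 members, camera called 22 on day 9 at midday and 31 at midnight, of which 1 and 4 held with an estimated correlation. On day 12 these were 21 and 28, of which 2 and 3 held. The families named here were picked from those called after their values were seen. Members of a family may share reads, so the loci counted below need not stand for as many separate Talinum genes. On day 9 at midday, of 32 loci annotated as peroxidases 23 fell (median -2.11, camera adjusted p = 1.67e-08, and adjusted p = 0.0138 with an estimated correlation), and of 37 GDSL lipases 27 fell and 2 rose (median -1.78, adjusted p = 5.75e-09, and adjusted p = 0.0532 with an estimated correlation). Pectin lyase-like proteins had 24 of 42 down and 6 up (median -1.35, adjusted p = 0.0663 with an estimated correlation), and invertase and pectin methylesterase inhibitors 12 of 15 down (median -1.92, adjusted p = 0.196 with an estimated correlation). The auxin-responsive SAUR family had 16 of 21 down and 1 up (median -1.36, adjusted p = 0.194 with an estimated correlation). Histones had 14 of 19 down (median -0.87, adjusted p = 0.4 with an estimated correlation), and leucine-rich repeat protein kinases 36 of 72 down and 7 up (median -0.70, adjusted p = 0.344 with an estimated correlation). Pentatricopeptide repeat proteins, which act on organelle RNA, had 54 of 137 up and 1 down (median 0.59, adjusted p = 5.64e-05, and adjusted p = 0.357 with an estimated correlation).

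After re-watering, against day 12 at midday, 27 of the peroxidases rose and 1 fell (median 2.97, adjusted p = 0.00183 with an estimated correlation), and 27 of the GDSL lipases rose and 2 fell (median 2.66, adjusted p = 0.00752 with an estimated correlation). The others given here did not hold with an estimated correlation. Of the methylesterase inhibitors 13 of 15 rose (median 2.46, adjusted p = 0.105 with an estimated correlation), of the pectin lyase-like proteins 23 of 42 rose and 7 fell (median 1.04, adjusted p = 0.105), and of the SAUR family 10 of 21 rose and 1 fell (median 1.23, adjusted p = 0.387). Of the leucine-rich repeat protein kinases 47 of 72 rose and 5 fell (median 1.26, adjusted p = 0.105). Of the pentatricopeptide repeat proteins 50 of 137 fell (median -0.54, adjusted p = 0.000182, and adjusted p = 0.42 with an estimated correlation).

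In the authors' deposited contig table, contigs without an Arabidopsis match were listed at a q-value under 0.01 most often on day 12, with 305 higher and 296 lower at midday and 360 higher and 297 lower at midnight. After re-watering 43 were listed at midday and 162 at midnight.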
